A study of Mus musculus with 6 samples.

How the data were processed

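RNA was measured by bulk sequencing in 6 libraries of flow-sorted live CD45+ CD4+ Foxp3+ cells from mouse colonic lamina propria, 3 from mice with a YFP-tagged Cre in Foxp3 (WT) and 3 from mice that in addition carried floxed Il23r alleles (KO), each a pool of at least 5 mice. Per the labels' protocols, RNA was extracted with a column kit for small samples and amplified with the Ovation RNA-Seq System V2, which starts from small amounts of total RNA, before library preparation with an NEB kit. Amplification from little RNA can lose rare transcripts from a library and enrich others, so that a low gene can be at 0 in one pool and well covered in another. Whether the libraries keep strand, and the genome build, the annotation and the step from transcripts to genes, are not given in the sources used here. No genome coordinates are printed for that reason.

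The deposited table held 32161 rows with a gene symbol, an Entrez identifier, an estimated count per library rounded to whole numbers, and the authors' comparison of the groups. The submitters' processing notes list fastp 0.20.0, Salmon 1.4.0, R 4.1.2 and DESeq2 1.34.0, with no role or order. The estimated counts were read as not normalized. Their totals differ between libraries, which by itself does not settle this. The authors' mean normalized signal, log2 fold change and its standard error, test score, p-value and adjusted p-value are read as such per the file headers. The authors' log2 fold changes are positive where KO is higher. A second deposited table had 6 columns of normalized values whose names match no sample, and these 6 columns were not used. Salmon estimates counts per transcript, and a count summed over transcripts keeps differences in transcript length between libraries that a length-corrected analysis would remove.

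Rows that share an Entrez identifier were summed, which took away 71 rows and left 32090 genes, and 32145 rows matched the RefSeq gene table of GRCm38.p6, used here for names, chromosomes and transcript numbers only. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which kept 12557 genes. Counts were scaled by TMM factors and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. CPM values use the TMM-scaled library sizes, log2 CPM values a prior count of 2, and the standard error of a log2 fold change is its size divided by the square root of the F statistic. DESeq2 1.42.0 and limma 3.58.1 served as alternatives, and adjusted p-values that DESeq2 left empty (5325 of 18841 genes) stayed empty. In a gene with 0 counts over a group, the fold is given against a floor of 3 counts over that group. Each sum was divided by the summed TMM-scaled library sizes of its group. This floor leaves out error in the other group's count. The lower limit of the exact two-sided 95% counting interval, which lies lower, is therefore given beside it. With 1 to 3 counts, or for Xist 6, the ratio of the group sums, scaled in the same way, is given with an exact 95% counting interval. Shares of counts carry 95% Wilson intervals. All of these intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. The p-values measure the spread between libraries, each a pool of mice by its label. If KO2 and KO3 shared material, a question taken up below, the spread within KO would be too small for independent pools.

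Ahead of the analysis, 40 gene lists were fixed for Treg programmes, metabolism, other cell types and sample quality. Of their 993 names, 982 were found in the table, and 38 lists had at least 5 tested members. They were tested with camera on voom values (limma) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, and members were also adjusted over the list alone. Named genes follow a rule fixed at the same time. It takes 10 genes in any case (Il23r, Foxp3, Il2ra, Ctla4, Il10, Ikzf2, Gata3, Abca1, Abcg1 and 1 that is not reported here), the 8 genes with the smallest p in each direction among those called without overlap between groups (filled up with uncalled genes, and without unnamed gene models), up to 4 members of each list that passed over all genes or over the list alone, up to 4 members with the smallest p of each list called by camera, and up to 3 of the most abundant members of such lists for other cells and sample quality. This gave 80 genes.

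Alternatives chosen before the data were examined were DESeq2 size factors, upper-quartile scaling, library size alone, no filter, a filter of 50 counts in 3 libraries, DESeq2's Wald test, limma-voom with quality weights, the replicate number as a block, sort batch as a term with all batches or with the batch of WT1 and KO1 against the rest, the RNA integrity number as a covariate, and each library left out in turn. Chosen after the data were seen were KO2 and KO3 summed into 1 library, genes on X and Y left out, and offsets that remove each library's trend with GC content and transcript length, taken from GENCODE M21 for 98.0% of tested genes.

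The tests were tried on simulated counts for KO against WT with the real means, dispersions and library sizes, in which 200 genes were changed. Of 12139 genes that passed the filter there, edgeR called 61 of 100 genes changed 4-fold, 13 of 100 changed 2-fold and 9 unchanged genes, while DESeq2 called 82, 29 and 52 in that order on 12557 genes. A simulated list of 30 genes shifted 2-fold was called by camera with the preset (adjusted p = 3.35e-24) and with the estimated correlation (adjusted p = 0.0107), and 0 of 37 unshifted lists were called by either. Genes and libraries were drawn independently there, with no pair made as close as KO2 and KO3. The simulation therefore does not show how often camera calls real lists whose members vary together.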

Results

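Regulatory T cells (Treg cells, CD4 T cells that carry the transcription factor Foxp3) were sorted by flow cytometry from the colonic lamina propria of untreated mice, and their RNA was sequenced in bulk. The WT group carried a YFP-tagged Cre recombinase in the Foxp3 gene, and the KO group carried the same Cre together with floxed alleles of Il23r, the gene of the interleukin-23 receptor. Each group had 3 libraries, and each library came from a pool of at least 5 mice, so that the spread between libraries is a spread between pools, as far as these are independent. Total estimated counts ranged from 9680503 in WT2 to 20654340 in KO1. RNA integrity numbers lay between 7.9 and 8.8 except in WT2, which had 5. WT1 and KO1 were sorted in one batch, WT2 and WT3 in another, and KO2 and KO3 each in a batch of its own.

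The first comparison asked whether Il23r (Entrez 209590) differed by genotype. Il23r was measured at 23.8 ± 12.9 CPM (TMM-scaled counts relative to library size, SD, n = 3) in WT and at 10.8 ± 6.88 CPM (SD, n = 3) in KO. The levels were 19.4, 38.3 and 13.6 CPM in WT1, WT2 and WT3, and 4.99 and 8.97 CPM in KO2 and KO3. The library labelled KO1 held 18.4 CPM, inside the WT range. The log2 fold change of KO over WT was -1.14 (SE 0.59), and edgeR's quasi-likelihood test did not call it (adjusted p = 0.573). An exact two-sided permutation test gave p = 0.2, where 3 libraries against 3 cannot give less than 0.1. A gene-level count adds up all exons and does not show whether a floxed exon was lost, and within the sort batch shared by WT1 and the library labelled KO1 the log2 difference was -0.08 while the other batches held 1 group each.

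The second comparison asked which genes differed between the colonic Treg cells of the WT and KO groups. Cathepsin E (Ctse, Entrez 13034), an aspartic protease of the endolysosomal system, fell from 153 ± 12.7 to 11.5 ± 5.59 CPM (SD, n = 3 each), a log2 fold change of -3.74 (SE 0.40), and was lower in all 3 KO libraries (edgeR, adjusted p = 0.0204). Fcgbp (Entrez 215384), a mucus protein made by goblet cells, rose from 1 count over the 3 WT libraries to 1733 counts over the 3 KO libraries, a ratio of 1199.5 after scaling by library size with a 95% counting interval of 215 to 47405 (edgeR, adjusted p = 0.0169). Xist (Entrez 213742), the non-coding RNA of the inactive X chromosome in female cells, rose from 6 to 116560 counts, a scaled ratio of 13446 with an interval of 6177 to 36641 (edgeR, adjusted p = 7.15e-05). These 3 were the genes called out of 12557 tested, 2 higher and 1 lower in KO, while 1176 genes had an unadjusted p under 0.05 and DESeq2 called 255 genes, 164 of them higher in KO. The groups did not overlap in 2221 genes, 17.7% of those tested, where chance gives 10% for 6 independent libraries. With KO2 and KO3, the closest pair, summed into 1 library, the share was 20.9% and chance gives 20%.

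The sex-linked genes differed between the groups as well as among the pools. Every KO library held Xist and no WT library had more than 5 counts of it. Sex and genotype therefore cannot be told apart for any gene or list compared here. Xist stood at 0.0943, 0 and 0.284 CPM in WT1, WT2 and WT3 and at 1182, 3472 and 2066 CPM in the library labelled KO1, KO2 and KO3. Summed over the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, expression was 264, 475 and 273 CPM in WT1, WT2 and WT3. It was 179, 2.19 and 72.8 CPM in the library labelled KO1, KO2 and KO3, or 53.0%, 0.65% and 21.6% of the WT mean. Tsix, the antisense transcript of Xist, had 0 counts in WT and 266 in KO, at least 61.4-fold higher, and its reads cannot be told from those of Xist without strand. Ddx3y was at 153 ± 68.3 CPM in WT and 28.4 ± 29.0 CPM in KO, and Kdm5d at 69.6 ± 20.9 and 23.5 ± 23.6 CPM (SD, n = 3), and neither was called. Of the 6 sex-linked genes tested, 1 rose, 0 fell and 5 did not pass over all genes, and 2 (Xist and Tsix) passed adjusted over the list alone.

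**Figure D1:**
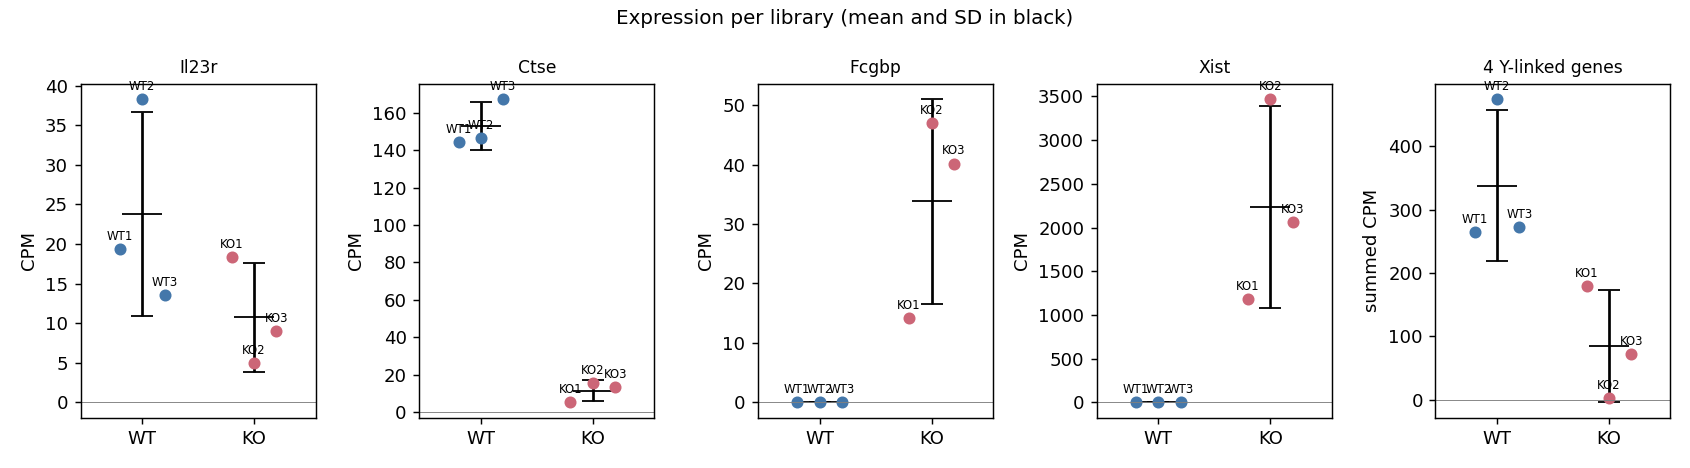
CPM in each library (points, by group on the x axis) with the group mean and SD (black), on linear y axes, for Il23r, Ctse, Fcgbp, Xist and the sum of 4 Y-linked genes. Ctse lay at 144 CPM or above in the WT libraries and at 15.8 CPM or below in the KO libraries, and the library labelled KO1 held Il23r at 18.4 CPM and Y-linked transcripts at 179 CPM.

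Below these 3 genes, the next by p among those higher in KO, leaving out unnamed gene models and pseudogenes, were Klk1b22, Serinc2, Echdc2, Zg16, Ell3 and Washc3, none of which passed in the main edgeR fit. In other edgeR fits Klk1b22 was called without a filter, with the stricter filter and without KO2, and Serinc2, Echdc2 and Ell3 were called without a filter. DESeq2 called all 6, with adjusted p from 1.23e-12 for Klk1b22 to 2.22e-05 for Zg16. Klk1b22, a kallikrein-family protease whose near-identical paralogs could share its reads, had 0 counts in WT and 1862 in KO, at least 429.6-fold higher, and narrowly missed the threshold (edgeR, adjusted p = 0.0537). Echdc2 was 109.6-fold (lower limit 88.8) and Ell3 102-fold (lower limit 82.6) higher against the floor, each with 0 counts in WT. Serinc2 and Zg16, a goblet-cell lectin, each had 1 count in WT and had ratios of 354 (counting interval 63.2 to 13997) and 248 (44.2 to 9814). Washc3, a subunit of the endosomal WASH complex, was at 3.83 ± 0.73 CPM in WT and 23.2 ± 4.75 CPM in KO (SD, n = 3). Those lower in KO with the smallest p after Ctse, again leaving out unnamed gene models, were Adnp, Dnajc2, Tbc1d8b, Ifi30, Mcm2, Ide and Lrrc8b. Their log2 fold changes ran from -0.96 for Ide, the insulin-degrading enzyme, to -1.77 for Mcm2, a subunit of the replicative helicase, and none passed (edgeR, adjusted p = 0.384 for each). DESeq2 called all 7, with adjusted p from 2.36e-05 for Tbc1d8b to 0.00631 for Ide. These genes were picked by their p in the same counts, and in the simulation DESeq2 also called 52 unchanged genes. Its calls are therefore not separate support. Ifi30, a lysosomal thiol reductase, was at 39.4 ± 2.06 CPM in WT and 15.01 ± 1.52 CPM in KO (SD, n = 3).

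Ctse and Fcgbp lost their calls without WT1, WT2, WT3 or KO3 in turn, with KO2 and KO3 summed into 1 library, and with the RNA integrity number as a covariate, leaving 1 called gene, Xist, in each of those fits. Fcgbp and Xist lost theirs in limma-voom with quality weights. The log2 fold change of Ctse stayed between -4.80 and -3.39 over the 21 alternatives, and that of Fcgbp stayed positive in each. Between WT1 and the library labelled KO1, the only batch with both groups, the log2 differences were -4.77 for Ctse, 6.80 for Fcgbp and 12.37 for Xist (prior count 2, 1 library each). With the 4 batches as a term the genotype estimate rests on that pair alone and the residual spread on WT2 against WT3. Its calls are therefore not counted as support, and Fcgbp was not called there.

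The genes that define Treg cells were also compared. Foxp3 was at 1043 ± 425 CPM in WT and 1365 ± 239 CPM in KO, Il2ra, a chain of the interleukin-2 receptor, at 948 ± 216 and 835 ± 225 CPM, and the inhibitory receptor Ctla4 at 2821 ± 357 and 2652 ± 128 CPM (SD, n = 3). The anti-inflammatory cytokine Il10 was at 1299 ± 222 and 1141 ± 70.0 CPM and the transcription factor Ikzf2 at 1042 ± 271 and 862.0 ± 230.1 CPM. The transcription factor Gata3 was at 642 ± 34.0 and 612 ± 193 CPM. None of these 6 genes was called, with edgeR adjusted p from 0.715 for Foxp3 to 0.946 for Gata3. Of 28 tested genes of the Treg core identity list 0 passed, with a median log2 fold change of 0.18, and of 22 suppressive effectors 0 passed, with a median of 0.12. The 14 IL-23 receptor signalling components had a median of -0.01, again with 0 passing over all genes or adjusted over the list alone. Camera called none of these 3 lists, with adjusted p of 0.490, 0.555 and 0.961 in that order, and the direction of the last test was up, against the sign of its median.

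In the list for the GATA3 and ST2 tissue programme, 0 of 24 genes passed over all genes and 1 passed adjusted over the list alone. It was Il1r2, a decoy receptor for interleukin-1, at 21.6 ± 1.31 CPM in WT and 55.5 ± 18.6 CPM in KO (SD, n = 3). Of 41 interferon-stimulated genes, 0 passed over all genes and 3 passed adjusted over the list alone, all higher in KO. Irf9, a transcription factor of interferon signalling, was at 35.0 ± 3.33 CPM in WT and 68.9 ± 2.24 CPM in KO, and Ifi27l2a was at 37.6 ± 13.7 and 85.2 ± 2.62 CPM (SD, n = 3). Oas2, an antiviral oligoadenylate synthetase, had 1 count in WT and 221 in KO, a ratio of 153 with a counting interval of 27.2 to 6069. Camera called neither list (adjusted p = 0.681 and 0.505).

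Abca1 and Abcg1, the transporters that export cholesterol from the cell, were followed as targets of the oxysterol receptor LXR. Abca1 was at 9.10 ± 4.37 CPM in WT and 19.3 ± 7.72 CPM in KO (SD, n = 3), with its highest level, 27.8 CPM, in the library labelled KO1. Its log2 fold change was 1.09 (SE 0.53) and was not called (edgeR, adjusted p = 0.549). Abcg1 was at 63.3 ± 21.7 and 57.2 ± 20.9 CPM, with an edgeR adjusted p of 0.925. In the authors' deposited table, the log2 fold change of Abca1 was 3.38 with an adjusted p of 6.67e-11, and that of Abcg1 was 0.18 with an adjusted p of 0.937. Of 26 tested genes in the list of LXR targets and cholesterol efflux, 0 passed over all genes or adjusted over the list alone, the median log2 fold change was 0.20, and camera did not call the list (adjusted p = 0.505). The authors' deposited table called 325 rows at the same threshold, 197 of them higher in KO, and these included Ctse, Fcgbp and Xist with adjusted p of 8.59e-13, 3.12e-10 and 7.12e-79 in that table.

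The third comparison tested the fixed gene lists, 38 of which had at least 5 tested members. Camera with a preset correlation of 0.01 called 9 lists, 5 higher and 4 lower in KO. With an estimated correlation it called 0, with an adjusted p of 0.753 for each of the 9 lists below. Fry called 0 lists for a shift in one direction (smallest adjusted p = 0.337) and 0 for a change in either direction (smallest adjusted p = 0.0683).

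The lists for ribosomal proteins, nuclear-encoded oxidative phosphorylation and glycolysis lay higher in KO, while the 13 mitochondrially encoded genes had a median log2 fold change of -0.38. The 24 fatty acid oxidation genes had a median of 0.0033 with 12 positive, and camera did not call them (adjusted p = 0.595). Of 42 cytosolic ribosomal protein genes, 39 had a positive log2 fold change with a median of 0.41, 0 passed singly, and the list was called (camera, adjusted p = 1.39e-07, against 0.753 with an estimated correlation, in a range over the alternatives of 6.36e-17 to 0.753). Examples were Rps13, at 401 ± 83.7 CPM in WT and 638 ± 85.0 CPM in KO, and Rps24, at 448 ± 78.8 and 715 ± 162 CPM (SD, n = 3). Of 39 oxidative phosphorylation genes, 29 were positive with a median of 0.54 and 0 passed (camera, adjusted p = 0.00198, range 0.000393 to 0.753). Cox4i1, a subunit of cytochrome c oxidase, was at 49.8 ± 22.4 and 125.5 ± 9.57 CPM, and Ndufa9, a subunit of complex I, at 8.80 ± 5.66 and 29.5 ± 4.14 CPM. Of 28 genes for glycolysis and hypoxia, 23 were positive with a median of 0.34, 0 passed over all genes and 1 adjusted over the list alone (camera, adjusted p = 0.00198, range 0.000240 to 0.753). That member was the glycolytic enzyme Tpi1, at 28.5 ± 9.11 and 72.3 ± 4.46 CPM, beside Aldoa at 169 ± 30.6 and 269 ± 48.7 CPM and Pkm at 207 ± 33.1 and 304.5 ± 38.2 CPM (SD, n = 3). Across genes, the log2 fold change correlated with GC content at a Spearman rho of 0.25, and after GC content and transcript length trends were removed the glycolysis list was no longer called (camera, adjusted p = 0.1002). Without WT2, the library of RNA integrity 5, the ribosomal list was not called (camera, adjusted p = 0.120), and with the RNA integrity number as a covariate neither the ribosomal list (0.103) nor the oxidative phosphorylation list (0.0520) was.

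The lists for cell division and for migration had negative medians and were called lower in KO by camera with the preset correlation, with members of each running the other way. In the cell cycle list 11 of 44 genes were positive, the median log2 fold change was -0.47 and 0 passed (camera, adjusted p = 0.0223, against 0.753 with an estimated correlation, range 0.000585 to 0.753). Mcm2 was at 33.2 ± 2.88 CPM in WT and 9.76 ± 3.32 CPM in KO, Mcm4, of the same helicase, at 61.6 ± 24.4 and 33.6 ± 2.17 CPM, and Kif23, a motor protein of cytokinesis, at 61.9 ± 5.81 and 37.1 ± 0.77 CPM (SD, n = 3). Rrm2, a subunit of ribonucleotide reductase, was at 19.5 ± 10.5 and 6.75 ± 3.32 CPM. Of 30 receptors for gut homing, retention and egress, 7 were positive with a median of -0.22 and 0 passed (camera, adjusted p = 0.00829, range 0.00211 to 0.753). The chemokine receptor Cxcr4 was at 549.5 ± 150.1 CPM in WT and 359 ± 45.9 CPM in KO, the integrin chains Itgal at 399.6 ± 63.2 and 285 ± 25.3 CPM, Itga4 at 650.0 ± 131.3 and 460.4 ± 56.9 CPM, and Itga1 at 23.0 ± 14.9 and 6.87 ± 2.96 CPM (SD, n = 3). The cell cycle call was lost without WT1 (adjusted p = 0.584), without the library labelled KO1 (0.0743) and with GC content and length trends removed (0.0594), all by camera. The migration call was lost without WT3 (camera, adjusted p = 0.278) and without the library labelled KO1 (0.115).

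Markers of other cell types that a colon preparation holds were called in 2 lists, both higher in KO. Of 26 macrophage, monocyte and dendritic cell genes, 24 were positive with a median log2 fold change of 0.78, and 0 passed (camera, adjusted p = 1.41e-06, against 0.753 with an estimated correlation, range 1.68e-11 to 0.753). Its most abundant members were Cd74, at 663 ± 231 CPM in WT and 770.3 ± 154.9 CPM in KO, H2-Aa, at 349 ± 103 and 419 ± 73.2 CPM, and H2-Ab1, at 239 ± 81.7 and 387 ± 69.9 CPM, which take part in antigen presentation. Those with the smallest p were Cst3, at 34.7 ± 10.7 and 68.0 ± 3.09 CPM, the complement gene C1qb, at 36.3 ± 7.65 and 70.3 ± 16.4 CPM, Itgax, at 7.48 ± 5.10 and 29.0 ± 15.01 CPM, and the Fc receptor Fcgr3, at 1.72 ± 0.96 and 8.14 ± 1.72 CPM (SD, n = 3). Of 15 epithelial genes, 12 were positive with a median of 0.51, 1 (Fcgbp) rose over all genes, 3 passed adjusted over the list alone, and 14 did not pass over all genes (camera, adjusted p = 0.0223, against 0.753 with an estimated correlation, range 0.00194 to 0.753). Clca1, a secreted goblet-cell protein, was at 0.948 ± 0.826 CPM in WT and 39.9 ± 15.5 CPM in KO, Krt8, a keratin of simple epithelia, at 1.14 ± 1.002 and 7.20 ± 1.64 CPM, and Lypd8 at 10.4 ± 8.70 and 21.8 ± 15.6 CPM (SD, n = 3). The 3 members lower in KO, named here after their values were seen, were Epcam, at 11.19 ± 6.09 and 6.04 ± 2.38 CPM, Cdh1, at 8.85 ± 7.71 and 3.45 ± 2.10 CPM, and Chga, at 2.04 ± 1.23 and 1.84 ± 0.253 CPM (SD, n = 3). None of these was called. The epithelial call was lost without WT1 (adjusted p = 0.160), WT2 (0.0878), WT3 (0.458) or KO3 (0.0777), and with the RNA integrity covariate (0.103), all by camera.

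The granulocyte and mast cell list had 4 tested genes, too few for camera, with 0 passing over all genes and 1 adjusted over the list alone. It was Csf3r, the receptor for granulocyte colony-stimulating factor, at 1.05 ± 0.56 CPM in WT and 7.60 ± 1.45 CPM in KO, beside Kit at 9.37 ± 1.95 and 16.9 ± 2.83 CPM and Ccr3 at 5.17 ± 3.49 and 9.62 ± 4.02 CPM (SD, n = 3). Plasma cell genes had a median log2 fold change of -0.64 over 11 genes and conventional CD4 effector genes one of -0.49 over 17 genes, and neither list was called (camera, adjusted p = 0.0502 for each). B cell, stromal, innate lymphoid and CD8 or natural killer markers were not called either, with camera adjusted p of 0.508, 0.582, 0.590 and 0.693.

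Among lists that mark sample handling, 2 were called, both lower in KO. Of 31 genes for dissociation and immediate-early stress, 11 were positive with a median log2 fold change of -0.14, 0 passed over all genes and 2 passed adjusted over the list alone, both lower in KO (camera, adjusted p = 0.0107, against 0.753 with an estimated correlation, range 1.60e-07 to 0.753). They were the chaperones Hsph1, at 1590.0 ± 499.3 CPM in WT and 797.5 ± 48.0 CPM in KO, and Hsp90aa1, at 3543 ± 1390 and 1475 ± 233 CPM (SD, n = 3). Hspa8 was at 4562 ± 1650 and 2595 ± 384 CPM, Dnaja1 at 2032 ± 394 and 1313 ± 85.9 CPM, and Hsp90ab1 at 2936 ± 696 and 1893 ± 132 CPM. The early-response genes Dusp1 and Zfp36l1, also among the most abundant, were at 4014 ± 1511 and 4001 ± 584 CPM and at 3598 ± 553 and 3707 ± 975.5 CPM. Of 13 mitochondrially encoded genes, 1 was positive with a median of -0.38 and 0 passed (camera, adjusted p = 0.00926, against 0.753 with an estimated correlation, range 6.26e-07 to 0.753). Their share of all counts was 7.39% in WT2 (95% Wilson interval 7.37 to 7.40) and from 3.07% in WT1 to 4.08% in KO2 among the other libraries, and without WT2 the list was not called (camera, adjusted p = 0.647). COX1 was at 28830 ± 16260 and 18770 ± 4538 CPM, ND5 at 3841 ± 1755 and 2533 ± 479 CPM, CYTB at 3207 ± 1034 and 2741 ± 498 CPM, and ND3 at 77.4 ± 26.1 and 35.7 ± 16.4 CPM. The stress call was lost without WT3 (adjusted p = 0.458) and without the library labelled KO1 (0.210), and the mitochondrial call without WT3 (0.0628), without the library labelled KO1 (0.210), with the RNA integrity covariate (0.673) and with GC content and length trends removed (0.0665), all by camera.

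Of 11 nuclear-retained or intron-rich transcripts, Xist alone passed, and Malat1, at 18950 ± 7383 CPM in WT and 17420 ± 5307 CPM in KO, and Lars2, at 4789 ± 1382 and 4607 ± 1499 CPM, did not (SD, n = 3). The 18S ribosomal RNA row Rn18s-rs5 took between 9.86% of counts in WT2 (95% Wilson interval 9.84 to 9.87) and 21.5% in KO2 (21.48 to 21.52). Camera did not call this list (adjusted p = 0.298), nor the sex-linked list (0.505). In all, 29 of the 38 tested lists were not called.

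**Figure D2:**
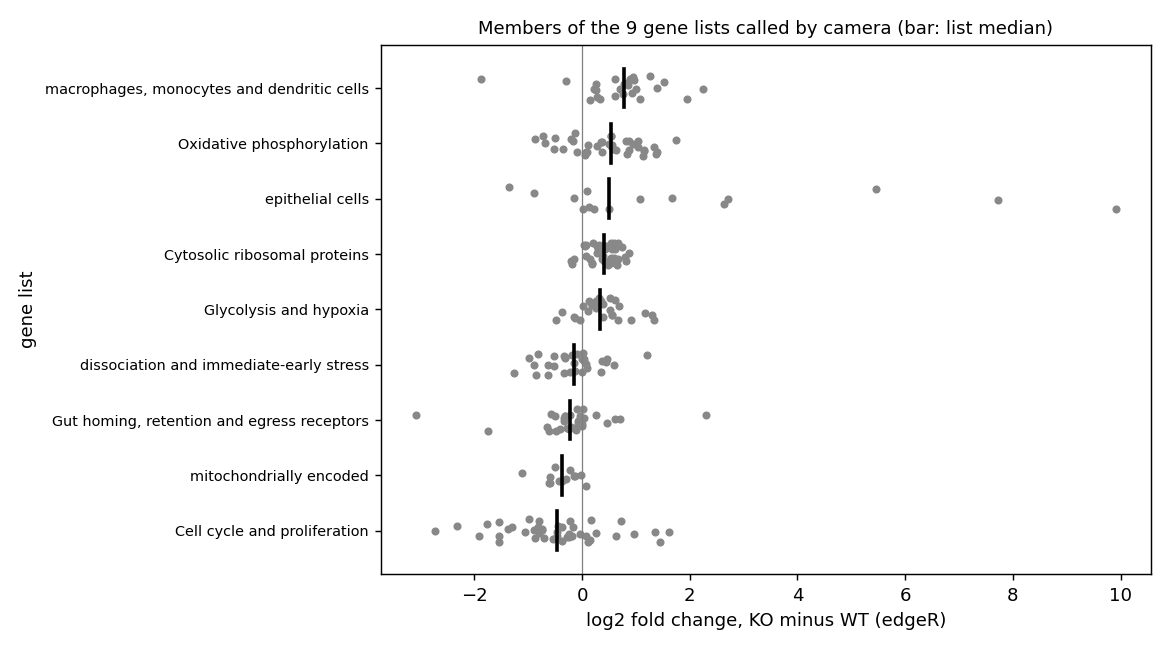
Each grey point is a tested gene of the list on the y axis, placed at its edgeR log2 fold change of KO over WT on the x axis, and each black bar is the list median. The medians of the 9 called lists run from -0.47 for the cell cycle list to 0.78 for the macrophage, monocyte and dendritic cell list, and the epithelial points farthest to the right are Fcgbp, Zg16 and Clca1.

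The KO2 and KO3 libraries resembled each other more than any other pair did. Over genes of intermediate expression, the median absolute deviation (MAD) of their log2 CPM difference was 0.193 (95% bootstrap interval 0.183 to 0.199), while the other 14 pairs ran from 0.386 for WT1 and KO1 to 0.693 for WT2 and KO3. They were kept as 2 libraries because the labels give them as separate samples and their Y-linked expression differed (2.19 and 72.8 CPM), with their sum as an alternative chosen after the data were seen.

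**Figure D3:**
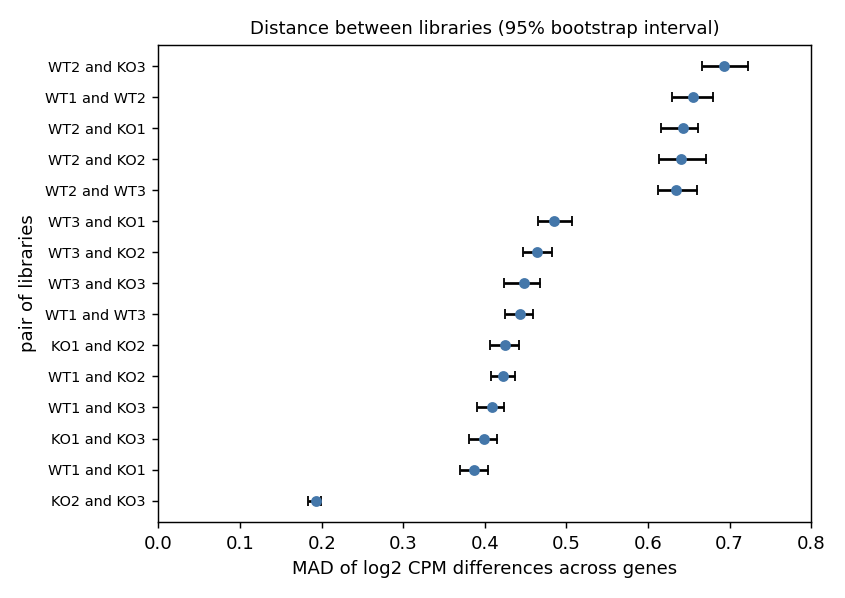
Each point is the MAD of log2 CPM differences between the pair of libraries named on the y axis, with its 95% bootstrap interval over genes (black). The pair of KO2 and KO3 lies at 0.193, and the next closest, WT1 and KO1, at 0.386.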

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

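Of 1673 refits of the 80 named genes under the alternatives, 1570 kept direction and side of the threshold, 15 lost a call, 47 gained one and 41 changed sign, the last in 15 genes. Only the 3 genes called in the main fit could lose a call. Ctse stayed called in 15 of 21 refits, Fcgbp in 13 of 21 and Xist in 19 of 20. The 3 called genes were also called under DESeq2 size factors, upper-quartile scaling, library size alone, sort batch A as a term, no filter, the stricter filter and DESeq2's own test. Without a filter edgeR called 9 genes (8 higher in KO), and DESeq2 called 255 genes (164 higher). With the RNA integrity number as a covariate 1 gene was called, and leaving out 1 library gave 1 to 4 genes. With KO2 and KO3 summed, an alternative chosen after the data were seen, as were those without X and Y genes and with GC and length offsets, edgeR called 1 gene and DESeq2 61. Limma-voom with quality weights called 2 genes, of which 1 (Ctse) was among the 3. Why these counts differ was not tested. Il23r kept a negative log2 fold change in all 21 alternatives, from -1.77 to -0.08, and was called in none. For gene lists, the count of 9 became 0 with an estimated correlation, 0 with fry in one direction, 0 with fry in either direction and 5 with the RNA integrity covariate, and leaving out 1 library gave 5 to 11 lists. None of the 153 refits of the called lists changed direction, and 48 lost the call. Those by fry in either direction have no direction of their own and could not change it.

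The replicate number as a block gave 3 genes and 10 lists. Same-numbered libraries did not deviate together (correlations of 0.01, 0.05 and 0.03), and WT1 correlated best with KO3 (0.05), so the numbers were not taken to pair the libraries.

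Sign changes, as log2 fold changes of uncalled genes whose cause was not tested, were as follows. With quality weights Il2ra had 0.0087, Gata3 0.041, Dusp1 0.019 and Lars2 0.12. With the 4 sort batches as a term, where genotype rests on WT1 and the library labelled KO1 alone, Abcg1 had 0.99, Itga4 0.041, Lypd8 -1.01, Zfp36l1 -0.49, ND5 0.14, ND6 0.063, CYTB 0.10, Rn18s-rs5 -0.10 and Kdm5d 0.036. With the RNA integrity covariate Abcg1 had 0.14, Zfp36l1 -0.11 and CYTB 0.030. With KO2 and KO3 summed Abcg1 had 0.0026, Zfp36l1 -0.060 (-0.072 in DESeq2) and Malat1 0.0047. With GC and length offsets, which moved the median of all genes by -0.12, Cd74 had -0.16 and Zfp36l1 -0.29. Dusp1 had 0.026 with upper-quartile scaling, 0.0066 with library size alone, 0.032 without a filter and 0.058 with the replicate block. Leaving out 1 library gave -0.29 to 0.15 for Gata3, -0.49 to 0.10 for Abcg1, -0.29 to 0.25 for Dusp1, -0.10 to 0.23 for Zfp36l1, -0.44 to 0.022 for CYTB, -0.40 to 0.16 for Malat1 and -0.25 to 0.20 for Lars2. The planned limma fit on the second deposited table was not run, since its columns match no sample. Depth limits the genes near 0 in WT, whose folds are bounds or wide intervals, and WT2 has both the lowest total (9680503) and the lowest RNA integrity (5).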

Other observations

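The tests of shared material, of shared genotype, of female cells and of a strain stretch were chosen only after the results they measure were seen, as was the repeat without 18S and mitochondrial counts. A set of 27 genes had at most 2 counts in each WT library and at least 20 in each KO library, and 0 genes showed the reverse. Beside Xist's antisense partner Tsix and the genes already described (Fcgbp, Klk1b22, Serinc2, Echdc2, Zg16, Ell3, Oas2), the set held, named here after their values were seen, the transcription factor Etv1, the glutamate transporter Slc1a2, the TNF-family ligand Tnfsf12, the haem-binding protein Hebp1 and Amn, which is part of an epithelial vitamin B12 receptor. In the library labelled KO1, KO2 and KO3, Etv1 was at 0.891, 9.19 and 6.02 CPM, Slc1a2 at 1.56, 3.41 and 1.76 CPM and Tnfsf12 at 13.6, 2.56 and 1.38 CPM. Of the 27 genes, 2 were in the epithelial list, 23 were called by DESeq2 and 1, Fcgbp, by edgeR. The set was picked from the same counts, so these calls are not separate support.

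For this set of genes, a candidate explanation was chance loss of rare transcripts in the WT pools, made easier if KO2 and KO3 act as 1 library. With all library totals thinned to 9680503 counts, 19 genes met the rule in the real split. At most 6 did in the splits that set KO2, KO3 and 1 WT library against the rest. With the 18S row and mitochondrially encoded genes removed and totals thinned to 8011347, the numbers were 16 and at most 5. These numbers argue against library total, or a loss alike in all libraries, as the whole cause. Thinning does not even out loss during amplification. At full depth, genes with at least 10 counts numbered 11380 to 12270 in the WT libraries and 12517 to 13027 in the KO libraries. WT1 and WT2 also had the lowest totals, though WT3 had a higher total than KO2 and KO3. These numbers therefore do not separate loss from depth. Greater loss of rare transcripts in the WT pools stays open. A stretch of foreign strain DNA around the targeted locus would place members on the chromosome of Il23r, which held 3.70% of them (95% exact interval 0.0937 to 19.0) against 5.21% of all tested genes. Female cells in the KO pools stay open: the median KO1 to KO2 ratio of the 24 autosomal members was 0.779 (95% bootstrap interval 0.418 to 1.30) and that of Xist 0.340, but members were picked for being present in the library labelled KO1, and since no WT pool held more than 5 counts of Xist, sex and genotype cannot be told apart. Genotype itself stays open and untested, and the library labelled KO1 had Il23r within the WT range.

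KO2 and KO3 lay far closer to each other than any other pair of libraries, and shared material between them is a candidate explanation. Of the 20 genes that KO2 held at 50 or more counts and WT1, WT2, WT3 and the library labelled KO1 did not hold at all, KO3 had 100% (95% exact interval 83.2 to 100), and KO2 had 12 of the 12 such genes of KO3, while the highest share in the remaining ordered pairs was 45%, for genes of the library labelled KO1 found in KO3. Depth is argued against, since with every library thinned to 9680503 counts the MAD of the pair was 0.190 and the next lowest 0.387. Shared genotype alone did not bring the WT libraries, also of one genotype by label, as close, with MADs of 0.443, 0.634 and 0.656 for their pairs. The values of 0.634 and 0.656 belong to pairs with WT2, the library of RNA integrity 5. WT2 lay 0.634 to 0.693 from every other library of either group, so WT1 and WT3, at 0.443, are the WT pair that bears on this. For the KO libraries shared genotype stays open. The closer of the distances from the library labelled KO1 was 2.07 times that between KO2 and KO3 (95% bootstrap interval 1.96 to 2.20). The Il23r level of the library labelled KO1 leaves in doubt whether it shares their genotype, and a gene-level count does not show whether a floxed exon was lost. KO3 held Y-linked transcripts and KO2 almost none, so they are not one library deposited under 2 names, and whether mice, cells or cDNA were shared stays open.

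The authors' log2 fold changes differed from those DESeq2 gave on the deposited counts by over 0.5 in 93 of the 296 tested genes their table called, Abca1 among them with a difference of 2.29. Library scaling is argued against, since the median difference over all genes compared was -0.0090. Length offsets from Salmon's isoform estimates would leave genes with 1 transcript in the authors' annotation nearly untouched. That annotation is not known, so RefSeq transcript numbers stood in for it, and only the more abundant tested genes were compared. Of 2248 genes with 1 RefSeq transcript 6.76% differed by over 0.5, and of 6998 genes with several 11.6%. The ratio of 0.581 lay between the bounds set beforehand, so that isoform length may account for part and stays open. The values of Abca1 therefore rest on which of these folds is read.

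The 6 libraries can be split 3 against 3 in 10 ways, the real one included, too few to give a share under 0.05. The real split gave 3 genes in edgeR and the others at most 0, and 1 of 10 splits reached the real count. In DESeq2 the real split gave 255 genes and the highest other 168, again with 1 of 10 as large. The 3 other splits that keep KO2 and KO3 on one side gave 114 to 168 genes in DESeq2, and the 6 that part them gave 3 to 10, which points to a structure of the samples. For gene lists, 2 of 10 splits gave as many as the real 9, and the other was the split of WT1, KO2 and KO3 against WT2, WT3 and the library labelled KO1, with 11 lists.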
